A study of Homo sapiens with 5 samples.

How the data were processed

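Chromatin immunoprecipitation of HIF-1α, the oxygen-regulated subunit of the transcription factor HIF-1, was followed by sequencing in K562 cells, an erythroid leukaemia line. Cells were kept for 72 h at 21% oxygen (normoxia) or 1% oxygen (hypoxia), with 2 ChIP libraries per condition, numbered 1 and 2 in the labels. An input library carried no processed values of its own and entered no comparison. The labels do not say whether the numbered libraries came from separate cultures.

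One list of regions was used per ChIP library, so regions had been listed per library and not on pooled libraries. The deposited values are FPKM, fragments per kilobase of region scaled by sequencing depth, per the file headers. BWA 0.7.17, MACS2, HTSeq and the build hg19 are named in the submitters' processing notes without a role or order. The calling threshold, the use of the input library and the treatment of reads that map to several places are not given in the sources used here. Each region and its FPKM are the authors' own.

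FPKM multiplied by region width was a whole multiple of a single step in 100% of non-zero regions of each library, within a tolerance of 0.02 steps. The step was taken as 1 read, which gives implied depths of 26.3 and 57.2 megareads for normoxia 1 and 2 and 134 and 65.4 megareads for hypoxia 1 and 2. These depths and all read numbers below rest on that assumption. Intervals are exact 95% binomial intervals (Clopper-Pearson) and cover counting error only.

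The FPKM column of hypoxia 2 did not belong to the regions on its rows. Its list has 1387 regions, of which the leading 776 carry an identifier, and 776 is the number of regions of hypoxia 1. FPKM times width had a Spearman correlation of 0.926 across regions with the hypoxia 1 reads on the same row, and of 0.0286 with the width of its own region. The values were therefore taken as reads of hypoxia 2 in the hypoxia 1 regions and divided by the widths of those regions. Hypoxia 2 thus has no value in regions that only its own list holds. The values as deposited were run as an alternative.

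Regions were placed in 5 classes: chromosome arms (chromosomes 1 to 22 and X, more than 1 Mb from a centromeric, variable heterochromatic or stalk band), centromeric or heterochromatic sequence, Y, mitochondrial, and unplaced or alternate sequence. Bands and chromosome lengths of hg19 came from circlize 0.4.16 and GenomeInfoDb 1.38.1. The classes and the 1 Mb margin were chosen after the data were seen.

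Lists were compared by overlaps of at least 1 bp (bedtools 2.31.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1), as a share of the shorter list and against 1000 random placements on the same chromosomes. The union of the 4 lists was merged at 1 bp and each union region scored for presence in each list. The number of regions was compared between conditions by a two-sided exact permutation test, for which 2 against 2 libraries cannot give a p below 0.33. FPKM in regions of all 4 lists was compared with limma 3.58.1 (R 4.3.3) with a trend on log2(FPKM + 1), Benjamini-Hochberg adjusted at 0.05, without a filter on low values except that regions at 0 in every library were left out. The FPKM of normoxia 1, normoxia 2 and hypoxia 1 refers to each library's own region and that of hypoxia 2 to the hypoxia 1 region, so widths differ between libraries at a site. No count model was used, since the values are not counts. Figures were drawn with matplotlib 3.10.9.

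The overlap procedure was tested on simulated lists: in 20 runs with 400 regions made hypoxia only, 399 to 401 were found. The limma fit was tested on 10 simulated regions per run. It recovered 66.8% of 2-fold, 99.2% of 4-fold and 100% of 8-fold changes, with 3.2% to 4.6% of unchanged regions called. The simulated noise was normal, with a common SD for every region and library. It held neither the noise of low read numbers nor widths that differ between libraries, so these rates need not hold for the real regions.

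Regions named in the text were chosen by a rule fixed before the data were examined: the 10 regions in both hypoxia and neither normoxia list with the highest mean hypoxia FPKM, the 5 in both normoxia and neither hypoxia list with the highest mean normoxia FPKM, and the 5 highest and 5 lowest hypoxia to normoxia ratios among regions of all 4 lists. Other named regions, the clusters and the chromosome and band summaries were chosen after the values were seen. The latter were also made with the regions of a set within 25 kb of one another taken as 1 locus. Planned parts that need genes or sequence (TET1, TET2 and TET3, gene lists, promoter shares and the hypoxia response element) were not run, because no hg19 genome or annotation was used here. Alternatives covered the overlap that counts as shared, merging, pseudocounts, a filter on low values, scaling, the replicate number as a block and leaving out each library.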

Results

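HIF-1α binding was profiled by ChIP-seq in K562 erythroid leukaemia cells after 72 h at 21% or 1% oxygen, with 2 libraries per condition, to ask where the factor sits on chromatin and which sites depend on low oxygen. HIF-1α is degraded in well-oxygenated cells and accumulates when oxygen is low. Implied depths were 26.3 and 57.2 megareads for normoxia 1 and 2 and 134 and 65.4 megareads for hypoxia 1 and 2. The lists were called per library by the authors. The labels do not name separate cultures, so the spread between these libraries may be technical. The limma and exact permutation tests compare libraries, and limma shares its estimate of spread across regions. The binomial, placement and Fisher tests take regions or loci as units, so their p-values do not measure spread between libraries.

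Hypoxia gave many more regions on the chromosome arms than normoxia. The hypoxia lists held 711 and 1333 arm regions and the normoxia lists 80 and 131. The means were 1022 ± 440 (SD, n = 2) and 105.5 ± 36.1 (SD, n = 2), a ratio of 9.69. The lower hypoxia count was 5.43 times the higher normoxia count, but the exact permutation test gave p = 0.33, the smallest that 2 against 2 libraries allow. Per 1e6 implied reads, the lists held 3.04 and 2.29 arm regions in normoxia 1 and 2 and 5.30 and 20.4 in hypoxia 1 and 2. By this measure hypoxia 2 carried most of the gap, but regions need not grow in proportion to depth. Listed arm regions held 0.0139% and 0.0143% of implied reads in normoxia 1 and 2 and 0.117% in hypoxia 1. Hypoxia 2 had 0.126% over the hypoxia 1 arm regions. These shares also grow with the number of regions counted. Over all listed regions the contrast was smaller, with 776 and 1387 regions in hypoxia against 646 and 480 in normoxia, a ratio of 1.92.

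The lists differed in where their regions lay. Arm regions made up 91.6% and 96.1% of the hypoxia lists, against 12.4% and 27.3% of the normoxia lists. In normoxia 1, 408 regions were centromeric or heterochromatic and 143 lay on unplaced or alternate sequence. In normoxia 2, 268 regions lay on Y, and 267 of these fell in one 98.2 kb stretch of Yq12 (58819458 to 58917638, hg19). Of the 268, 262 were listed at an FPKM of 0. Counted as loci, with regions within 25 kb of one another taken as 1 (chosen after the data were seen), the lists held 43, 30, 31 and 34 loci outside the arms in normoxia 1, normoxia 2, hypoxia 1 and hypoxia 2. On the arms they held 39, 111, 567 and 1049. Of the arm regions, 53.8% in normoxia 1, 13.7% in normoxia 2 and 8.86% in hypoxia 1 were listed at 0.

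**Figure D1:**
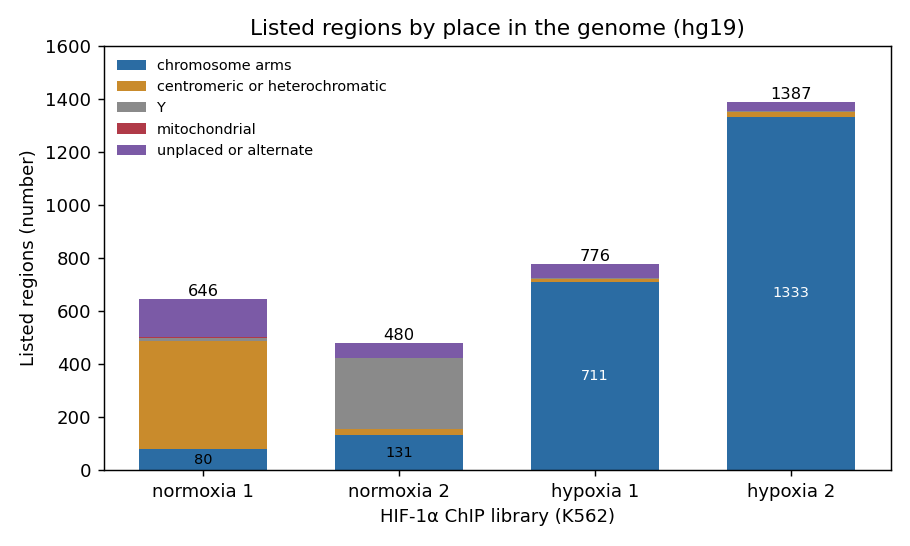
Number of listed regions (vertical axis) in each HIF-1α ChIP library (horizontal axis), stacked by place in hg19, with the total above each bar and the arm regions inside it. Arm regions number 80 and 131 in normoxia and 711 and 1333 in hypoxia.

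Of the 776 hypoxia 1 regions, 541 (69.7%, 95% interval 66.3 to 72.9) overlapped a hypoxia 2 region, while 537 of the 1387 hypoxia 2 regions overlapped one of hypoxia 1. The Jaccard index of the 2 lists was 0.380. Random placement gave a mean of 0.133 overlaps among placeable regions, where 517 were observed (permutation of positions, p = 0.001, the smallest that 1000 placements can give). By reads in the hypoxia 1 region, the share was 38.8% (31.6 to 46.3) in the lowest quartile of arm regions and 97.2% (93.6 to 99.1) in the highest. The normoxia libraries shared 51 of 480 regions (10.6%, 8.01 to 13.7), and 17 of 80 on the arms (21.3%, 12.9 to 31.8). As a share of the shorter list, overlap on the arms did not follow condition. That list held 711 regions for the hypoxia pair and 131 for normoxia 2 with either hypoxia library. The hypoxia pair shared 71.9%, while normoxia 2 shared 75.6% with hypoxia 1 and 76.3% with hypoxia 2. Normoxia 1 shared 22.5% with hypoxia 1 and 17.5% with hypoxia 2. The Jaccard index on the arms was 0.382 for the hypoxia pair. It was 0.110 and 0.0655 for normoxia 2 with hypoxia 1 and 2, and 0.0564 for the normoxia pair. For normoxia 1 with hypoxia 1 and 2 it was 0.0129 and 0.0054. By this index the hypoxia pair stood apart and the normoxia pair did not. Both measures depend on the lengths of the lists. Every pair of libraries had the same p for random placement, so that test does not group libraries by condition.

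Over the hypoxia 1 regions with reads in both hypoxia libraries (641), FPKM differed by less than 2-fold in 541 (84.4%). The median log2 difference, hypoxia 2 over hypoxia 1, was -0.04 with an SD of 0.73 across regions. Arm regions of hypoxia 1 that the hypoxia 2 list lacked (200) had a median FPKM of 2.63 in hypoxia 2, against 8.79 in the 511 that it held. More than 3 hypoxia 2 reads were present in 129 of those 200 regions, so absence from a list was not absence of reads.

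**Figure D2:**
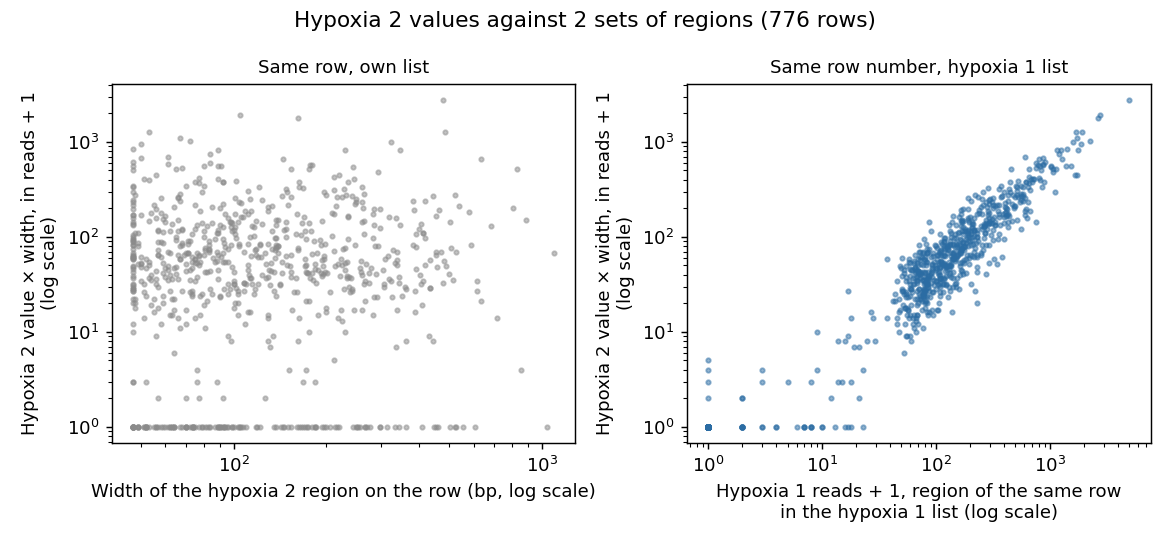
Reads implied by the hypoxia 2 values (vertical axes, log scale, plus 1) against the width in bp of the hypoxia 2 region on the same row (left, log scale) and against hypoxia 1 reads in the region on the same row of its own list (right, log scale, plus 1), one point per row for 776 rows. The rank correlation across regions is 0.0286 on the left and 0.926 on the right.

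The main question of the design is which sites appear under 1% oxygen. Of 516 union regions in both hypoxia lists, 424 (82.2%) were in neither normoxia list, 407 of them on the chromosome arms. On the arms, normoxia 1 and 2 held only 78 and 119 union regions, against 491 in both hypoxia lists. Most of the 491 would thus be in neither normoxia list even at full overlap, so the share reflects list length. The normoxia libraries have values only in their own listed regions. Their signal in these hypoxia-only regions is therefore unknown, and absence from their lists is not absence of binding. Presence in normoxia 2 differed with read number: by hypoxia 1 reads, 4.49%, 2.25% and 4.52% of hypoxia 1 arm regions in the lower 3 quartiles were listed there, against 37.6% in the highest. By region width the shares were 4.49%, 0.562% and 5.65%, against 38.2% in the highest quartile. Reads are totals over a region, so signal and width were not separated. The reverse pattern, both normoxia lists and neither hypoxia list, held for 25 regions, 4 of them on the arms. The other library pairs shared 1 to 6 regions exclusively over all regions. On the arms they shared 1 to 5, so the 4 of the normoxia pair did not stand out there. With 3 ways to split 4 libraries into pairs, no p-value below 0.05 is possible. Keeping the regions at or above the median width of each list gave 265 hypoxia-only regions and keeping equal numbers of the widest regions gave 224, both chosen after the data were seen. Equal numbers do not make the arm lists equal, since 349 of the 480 normoxia 2 regions lay outside the arms. Requiring only the remaining hypoxia list gave 1277 without hypoxia 1 and 669 without hypoxia 2. For the reverse pattern, requiring only the remaining normoxia list gave 358 without normoxia 1 and 610 without normoxia 2.

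The 10 hypoxia-only regions with the highest mean FPKM included 4 in 22q11.21. The highest, at 22q11.21 (chromosome 22, 18989808 to 18990218), had an FPKM of 19.7 ± 3.92 (SD, n = 2). The other 22q11.21 regions began at 21336525 (18.2 ± 0.392), 21132039 (16.9 ± 5.95) and 21221775 (16.6 ± 3.51). A region of 22q12.2 (30819872 to 30820410) had 19.4 ± 10.9, with 11.6 in hypoxia 1 and 27.1 in hypoxia 2. Regions of 19q13.11 (33615494 to 33616003) and 1p36.22 (11989940 to 11990188) had 16.6 ± 3.90 and 16.3 ± 0.226. The 17q21.32 region (45307235 to 45307413) had 17.05 ± 6.66 and the 17q25.3 region (78865633 to 78866146) 16.2 ± 12.4. The remaining one lay on an unplaced chromosome 7 sequence, with 18.7 ± 3.58. All 10 lay more than 1 kb from any normoxia region, and 6 of them were hypoxia only at 50% reciprocal overlap. With only the regions at or above the median width of each list 4 remained in the set, and with equal numbers of the widest regions 5.

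The 5 normoxia-only regions with the highest mean FPKM all lay outside the arms. Those on the unplaced sequence Un_gl000220 had FPKM of 30.3 and 138 (117792 to 117882) and of 45.4 and 54.3 (119020 to 119213) in normoxia 1 and 2. Those at 4p11, 16p11.2 and 2p11.1 had means of 5.69, 3.66 and 0.662. The 4 normoxia-only arm regions held at most 1 read in either normoxia library. Un_gl000220 also held regions of all 4 lists, among them 116993 to 117579, listed at 0 in every library. The normoxia-only regions there therefore do not set that sequence apart by condition.

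Part of the hypoxia sites were also listed in normoxia. Of the 119 arm regions of normoxia 2 in the union, 93 (78.2%) were in at least 1 hypoxia list, against 18 of 78 (23.1%) for normoxia 1. In the 81 arm regions listed in both hypoxia libraries and normoxia 2 with normoxia 2 reads, median FPKM was 8.02 in normoxia 2, 11.6 in hypoxia 1 and 15.1 in hypoxia 2. FPKM was higher in both hypoxia libraries in 59 of the 81. With the hypoxia 2 values as deposited the number was 6. The normoxia 2 regions were narrower at these sites, with a median of 135 bp against 398 bp in hypoxia 1, so the FPKM values refer to different widths. Among them, 9q33.2 (chromosome 9, 123659254 to 123659927) had 12.9 in normoxia 2 and 27.6 and 37.4 in hypoxia, and 8q24.22 (chromosome 8, 134387574 to 134388245) had 10.5 against 23.7 and 24.7. These 2 regions were chosen after their values were seen.

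In the 10 regions of all 4 lists with a value, 2 were higher in hypoxia and 0 lower by limma at an adjusted p of 0.05, with 3 at an unadjusted p under 0.05. A 19q13.11 region (chromosome 19, 34849804 to 34850770) had FPKM of 13.3 and 17.4 in normoxia and 38.6 and 43.6 in hypoxia, a log2 difference of 1.37 (SE 0.29, limma adjusted p = 0.00136). A 2p11.2 region (chromosome 2, 86667703 to 86668530) had 18.98 and 13.4 against 27.9 and 40.0, a log2 difference of 1.02 (SE 0.31, limma adjusted p = 0.0195). Widths differed at both sites. At 2p11.2, normoxia 1 had 23 reads over 46 bp, normoxia 2 336 over 439 bp and hypoxia 1 2751 over 736 bp. At 19q13.11, they had 84 over 239 bp, 555 over 557 bp and 5003 over 967 bp. Differences are on the log2(FPKM + 1) scale. A 17q25.3 region (80188594 to 80189227) had a log2 difference of 1.13 (SE 0.48, limma adjusted p = 0.0963). The other 17q25.3 region (80415797 to 80416649) and the 1p36.23 region (8938005 to 8939601) had log2 differences of 0.49 and 0.37. The 5 lowest were 15q26.1 (0.10), 19q13.32 (0.01), 6p21.1 (-0.00), 8q13.3 (-0.09) and 1p22.2 (-0.30). Both of the last held at most 3 reads in any library.

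Several alternatives ended these calls. With the replicate number as a block, neither the 19q13.11 nor the 2p11.2 region passed (limma adjusted p = 0.116 and 0.276), nor did they with the regions at 0 in every library kept (0.118 and 0.398), while the log2 differences stayed at 1.37 and 1.02. Neither passed without normoxia 1 (0.125 and 0.157), with log2 differences of 1.19 and 1.26, or without hypoxia 2 (0.0631 and 0.495), with 1.28 and 0.77. The 2p11.2 region also failed without normoxia 2 (0.207, log2 difference 0.78) and with library medians set equal (0.0843, log2 difference 0.64). With the hypoxia 2 values as deposited, 0 regions passed and the 19q13.11 difference was -0.45. Those values do not follow the regions on their rows, so this alternative is not a test of the calls.

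**Figure D3:**
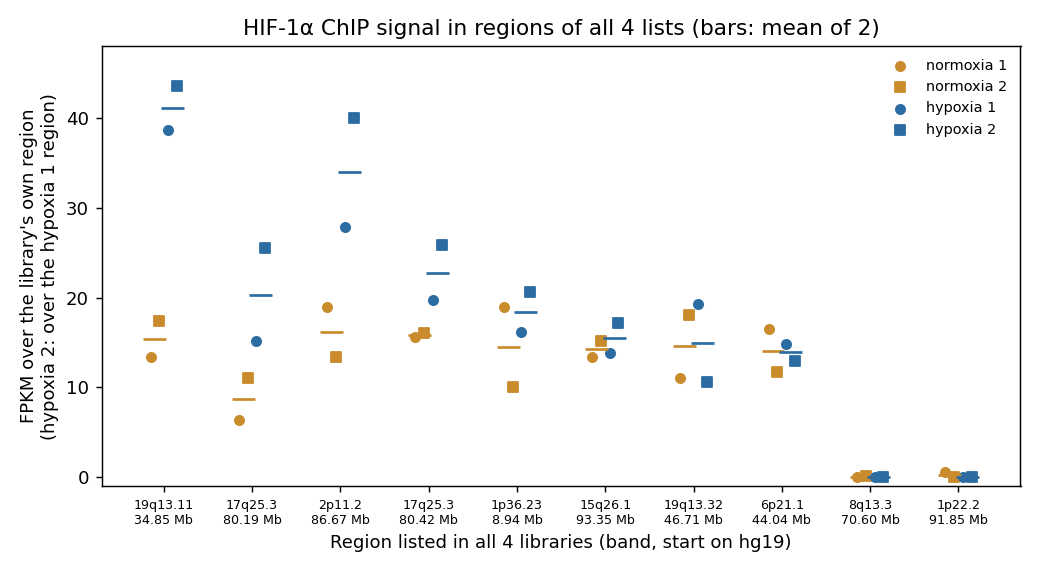
FPKM (vertical axis) of each library in the 10 regions of all 4 lists with a value (horizontal axis, band and hg19 start), one symbol per library and bars for the mean of 2. At 19q13.11 hypoxia has 38.6 and 43.6 and normoxia 13.3 and 17.4.

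Hypoxia sites were unevenly spread over the genome. The 491 arm regions in both hypoxia lists came to 0.177 per Mb. Expected numbers per chromosome rest on arm length alone and take no account of gene content or copy number. Chromosome 19 held 39 against 7.93 expected from its arm length (4.92 times, exact binomial test, adjusted p = 2.16e-14 over 23 chromosomes). Chromosomes 22, 17 and 1 were also above expectation (2.61, 2.02 and 1.80 times), and 5, 13, 20 and X below (0.550, 0.417, 0.296 and 0.380 times). With regions within 25 kb taken as 1 locus (431 loci, chosen after the data were seen), 19, 22, 17 and 1 were still above (4.31, 2.78, 2.04 and 1.79 times) and X below (0.433 times). Chromosomes 5, 13 and 20 no longer passed, at 0.590, 0.407 and 0.337 times (exact binomial test, adjusted p = 0.0929, 0.0622 and 0.104).

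Giemsa-negative bands, which are rich in genes, held 67.6% (63.3 to 71.7) of the arm regions in both hypoxia lists against a mean of 45.4% for random placements (adjusted p = 0.0024 over 6 sets), and 67.3% (62.6 to 71.7) of their loci. Regions of hypoxia 1 alone and hypoxia 2 alone had 63.4% and 64.5% (62.2% and 64.9% as loci), and those of normoxia 2 and any hypoxia list 78.5% (77.0% as loci). These 4 sets were above random either way. Of the 22 regions of normoxia 2 alone, 72.7% lay in such bands (adjusted p = 0.02), and of its 21 loci 71.4% (adjusted p = 0.0408). Normoxia 1 alone was above random only by regions, which lay close together. Of its 56 regions 42 lay in Giemsa-negative bands (75%, adjusted p = 0.0024), but of its 22 loci 12 did (54.5%, 32.2 to 75.6), against a random mean of 45.5% (adjusted p = 0.53).

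In 7 places at least 3 regions of both hypoxia lists lay within 25 kb of one another. At 6p21.1, 4 such regions fell within 18.5 kb (chromosome 6, 44026190 to 44044707), 3 of them also in normoxia 2 and 1 in normoxia 1. At 4q22.1, 3 regions in 9.63 kb (89735419 to 89745052) were in neither normoxia list, as were 3 at 16p11.2 (30552466 to 30560410) and 3 at 12q24.31 (125401747 to 125423932).

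**Figure D4:**
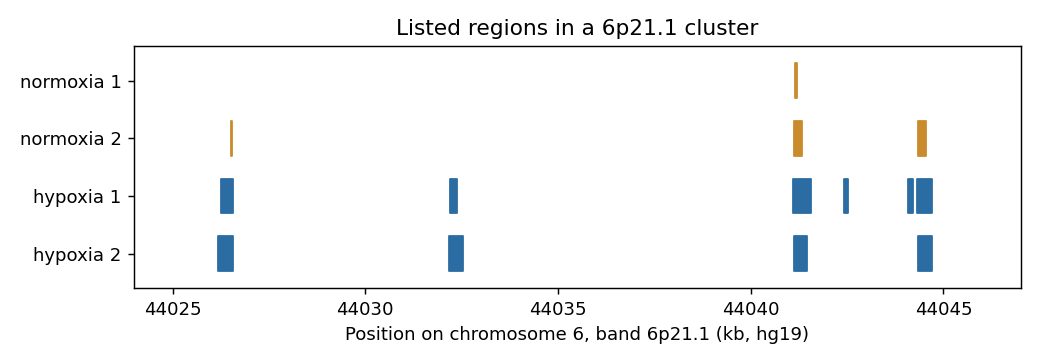
Listed regions of each library (rows) along chromosome 6 at 6p21.1 (horizontal axis, kb, hg19), drawn to scale as bars. Of the 4 sites in both hypoxia libraries, 3 are also in normoxia 2 and 1 in normoxia 1.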

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

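The tests in this part were chosen after the results were seen.

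Mitochondrial regions stood out in normoxia 1 as data outside the comparisons. Its list had 5 mitochondrial regions with 150887 reads, 54.7% of its listed reads and 0.573% of its implied depth, and the other 3 lists had none.

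The hypoxia 2 values did not follow the regions on their rows. If the regions listed at 0 truly lacked reads, hypoxia 1 regions overlapping them would hold no hypoxia 2 reads, yet 214 of 247 held more than 3, with a median of 75 reads. That count takes the values to belong to the hypoxia 1 regions, so it is not independent of the next one. The rank correlation of 0.926 with hypoxia 1 reads on the same row is what values counted over the hypoxia 1 regions and placed beside another list would give. No biological explanation was tested.

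The normoxia lists lay mostly outside the chromosome arms by number of regions. By loci, normoxia 1 had 43 outside and 39 on the arms and normoxia 2 had 30 and 111, since 267 regions of normoxia 2 form a single Yq12 run. Reads that map to several places, used for calling and not for counting, may account for part of the normoxia 2 regions there. Of its 30 loci outside the arms, 46.7% had every region at 0, against 14.4% of 111 arm loci (two-sided Fisher's exact test, p = 0.00064), and without Y 58 of 81 regions outside the arms were at 0. Hypoxia 1 also had 21 of 31 such loci at 0, so this does not set normoxia apart. In normoxia 1 the shares were 14.0% of 43 loci and 41.0% of 39 arm loci (Fisher's exact test, p = 0.0068) but 50.5% and 53.8% by regions, and larger loci are less often wholly at 0, so the question stays open there, as does an effect of oxygen.

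Arm regions were more numerous in hypoxia. At near-equal depth (0.874), normoxia 2 had 0.0983 (95% interval 0.0815 to 0.118) of the arm regions of hypoxia 2, which argues against depth as the whole cause of that gap. The other pairs differ too much in depth to decide, since regions need not grow in proportion to it: normoxia 2 had 0.184 of the arm regions of hypoxia 1 at 0.426 of its depth, and normoxia 1 had 0.113 of those of hypoxia 1 at 0.196 and 0.06 of those of hypoxia 2 at 0.403. In shared regions, FPKM was higher in both hypoxia libraries than in normoxia 2 in 59 and lower in both in 13. Regions of a single normoxia library are not replicates of the condition. More HIF-1α at its sites and a less efficient immunoprecipitation in normoxia both predict higher FPKM in hypoxia, so this count cannot tell them apart.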

How the results depend on the processing

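Rankings and restrictions by width, chromosome arms only, merging within 25 kb, the hypoxia 2 values as deposited, regions at 0 kept and the crossed pairing were chosen after seeing the data. The planned rankings by FPKM (upper part, equal numbers) were not run, since hypoxia 2 has no values for its own regions. Gene lists, promoter shares and motif tests were not run, because no hg19 annotation or genome was used here. The cause of the changes below was not tested, except where fewer regions or libraries make them.

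Merging regions within 500 bp left 283 regions in normoxia 1 and 181 in normoxia 2, and the arms alone 80 and 131. Merging within 25 kb left 82 and 141. The hypoxia counts stayed within 1.5 times. Overlap of the hypoxia libraries was 47.0% at 50% reciprocal overlap, 76.7% within 1 kb, 80.7% for regions at or above the median width of their list and 64.8% for equal numbers of the widest regions. That of the normoxia libraries was 5.0% at 50% reciprocal overlap and 21.25% on the arms. Hypoxia-only regions numbered 265 at or above the median width and 224 at equal numbers, and 425 to 1277 leaving out each library. Normoxia-only regions numbered 16 within 1 kb, 12 at or above the median width and 4 on the arms, and 25 to 610 leaving out each library. With the replicate block, 487 regions were listed or higher in hypoxia in both same-numbered pairs and 31 in normoxia.

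By limma, 1 region was higher in hypoxia with library medians equal, 1 with the replicate block, 0 with hypoxia 2 as deposited, 0 with regions at 0 kept, and 0 to 2 leaving out each library, when 0 to 1 were lower. A lone library was then assumed to vary like the other group. The lower regions were 8q13.3 without normoxia 1 and 1p22.2 without normoxia 2, and both held at most 3 reads in any library. The libraries were not taken as paired by number (correlation of deviations -0.13), which 10 regions and 2 pairs leave open. The block called the 17q25.3 region at 80188594 in place of the others. A crossed pairing called 2 regions higher and 0 lower. The 19q13.11 call passed in 7 of 12 alternatives (adjusted p 9.15e-06 to 0.789) and 2p11.2 in 5 of 12 (0.000392 to 0.952).

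Directions turned with hypoxia 2 as deposited at 1p36.23 (-0.71), 1p22.2 (1.24), 15q26.1 (-1.83), 17q25.3 at 80415797 (-1.85), 19q13.11 (-0.45) and 19q13.32 (-1.07). The deposited values do not follow the regions on their rows, so these turns are not a test of the directions. With medians equal, directions turned at 1p36.23 (-0.009), 15q26.1 (-0.28) and 19q13.32 (-0.37). That setting lowers every region's difference by the same amount, so small positive differences turn by construction. Leaving out each library gave -0.054 to 0.80 at 1p36.23, -0.62 to 0.028 at 1p22.2, -0.041 to 0.25 at 15q26.1, -0.39 to 0.42 at 19q13.32 and -0.23 to 0.23 at 6p21.1.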

Other observations

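The patterns in this part were noticed in the data, and the 22q11.21 comparison was chosen after the values were seen.

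Normoxia 1 had dense runs of regions that neither hypoxia list overlapped. At 16q11.2, 83 regions lay within 48.7 kb (46386857 to 46435527) and at 2p11.1, 79 within 57.1 kb (92269077 to 92326150). On the arms, 18 regions lay at 1p36.33 (564491 to 570280), 14 of them at 0. At 3p21.1, 6 regions with 152 reads lay within 4.11 kb (52437190 to 52441300), and at 5q31.1, 6 with 591 reads within 3.85 kb (134259852 to 134263697).

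Of the 10 hypoxia-only regions with the highest FPKM, 4 lay in 22q11.21. Among bands with at least 5 hypoxia 1 arm regions of more than 3 reads, it ranked 1 of 30 by median FPKM, so no p-value is given for it. Its 11 hypoxia 1 regions had a median of 13.4 in hypoxia 1, against 8.02 for 622 regions elsewhere, and 15.3 against 7.53 in hypoxia 2. The 4 named union regions of the band span 5 of these, since the one at 21221775 covers 2. Without the 10 named regions, the 6 left in the band had 1.53 times the median elsewhere in hypoxia 1 and 1.63 times in hypoxia 2. K562 carries extra copies of part of 22q11, and a hypothesis is that these raise every region there. Stronger binding predicts the same values, and repeated sequence in the band was not tested. Without input values these cannot be told apart.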
